A study of Mus musculus with 16 samples.

How the data were processed

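Livers of female B6C3F1 mice given furan in corn oil or corn oil alone were measured on Agilent SurePrint G3 mouse arrays, per the labels with 4 biological replicates in each dose group, at 2 times in formalin. Per the labels the design was a reference design with randomized blocks, RNA came from paraffin sections, the liver sample was labelled with Cy5 and a pooled reference with Cy3 on every array, and no dye swap was made. The authors scanned the arrays and read them with Agilent Feature Extraction 11.0.1.1. The deposited scanner files give median spot and background signals as intensity, with no normalization, and processed signals as intensity after background subtraction and dye normalization. Per the file headers they also give Agilent's log ratio of sample over reference in log10 units. The deposited value table holds log2 sample over reference per probe after an intensity-dependent normalization by the authors whose method is not stated. Its scale and direction were settled from the values, and it was used only as an alternative. Its column medians were 0.000797, 0.00330, -0.00510 and 0.00438 for 18 h controls 2, 3, 4 and 6, and 0.0247, 0.0204, 0.0163 and 0.0187 for 18 h furan samples 41 to 44. At 3 weeks they were -0.00872, -0.00919, -0.00159 and -0.00869 for controls 2.1, 2.2, 4 and 6, and -0.00715, -0.00825, -0.00445 and -0.00133 for furan samples 41 to 44.

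Median signals were used because the files give no mean signals. Of 62976 spots per array, 59305 were not controls and stood for 55681 probes. Background was corrected by normexp with an offset of 50, ratios were normalized by loess within each array, and spots marked as non-uniform or as outliers, between 187 and 308 per array, were left out. Spots of a probe were averaged. A probe was kept if it was well above background in the sample channel on at least 3 arrays of at least 1 group, and each gene was represented by its kept probe with the highest mean brightness. The files name mouse build mm9, and 27235 probes were matched by accession to RefSeq gene symbols, while 28446 were not. No genome was used, so probe sequences were not mapped and positions are not given.

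R 4.3.3 with limma 3.58.1 fitted each gene with the slide as a term and moderated the variances (lmFit and eBayes), and p values were two-sided and adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. The furan comparisons used the samples of their own time in formalin, and the difference between the times and the comparison of the times used all 15 samples. The 3-week control arrays 2.1 and 2.2 were averaged first because they share the sample number 2, which was read as 1 animal. The average took a slide value midway between the slides. Gene lists were tested by camera with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry, which tests whether the genes of a list move on balance in 1 direction and compares them with no other genes. Mitochondrially encoded genes had too few measured members to test, which left 34 lists. Signal measures were compared by exact permutation of the samples in R. The figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9. Where a named gene was not well above background on any array of a group, this is said with its value, since its fold is then poorly determined.

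The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took, in each furan comparison and in the comparison of times, the 10 largest rises and 10 largest falls among called genes whose groups do not overlap, up to 4 members with the smallest p from each described list, and 8 genes whatever their values. From each list fewer than 4 members were then taken by this rule. A gene that the rule named is not reported here, and no other gene took its place. The alternatives covered background correction, normalization, the authors' values, filters, probes per gene, slide, variance model, array weights, thresholds, the reading of arrays 2.1 and 2.2, the pairing of numbers and leaving out each replicate. A covariate for the share of probes above background and the use of each gene's next brightest probe were added after seeing the data.

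The fits were tested on simulated data of 22013 genes with 200 changed. At 2-fold they recovered 97.0% of changed genes for furan at 18 h, 56.7% for furan at 3 weeks, 67.2% for the difference and 100% for the time in formalin. False calls made up 5.49%, 7.14%, 13.5% and 4.08% of the calls. The simulated genes varied independently, with no slide or array-wide effect, so these rates may not hold in the data.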

Results

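The series measured RNA from fixed livers of female B6C3F1 mice, a hybrid strain widely used in toxicology. Furan, a small volatile compound that liver cytochrome P450 turns into a reactive metabolite, was given by oral gavage at 8 mg per kg body weight in corn oil for 21 days. Controls received corn oil alone, and liver was taken 4 h after the last dose. The tissue stayed in formalin for 18 h or for 3 weeks before it was embedded in paraffin. RNA came from 1 section per liver at 18 h and from 2 sections at 3 weeks, so the number of sections changed together with the time in formalin. Each of 16 arrays carried a liver sample in Cy5 and a pooled reference in Cy3, with 4 arrays in each of 4 groups. The 3-week control arrays numbered 2.1 and 2.2 share the sample number 2 and correlated at r = 0.93 across genes. The labels do not say whether they came from the same animal. They were read as 1 animal and averaged, which left 15 samples and 3 control samples at 3 weeks. The number of arrays limits the precision of every value. The arrays lay on 2 slides, each with 2 arrays of every group.

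Each array measured 55681 probes, of which 29690 were bright enough to test, and these stood for 22024 genes or transcripts, 13052 of them with a gene symbol. The share of probes well above background was 44.3% to 50.1% in controls and 51.9% to 55.2% with furan at 18 h, and 32.3% to 36.7% in controls and 35.9% to 41.4% with furan at 3 weeks. The median signal over background reached 2.65 in 18 h controls, 2.67 in 18 h furan samples, 2.44 in 3-week controls and 2.28 in 3-week furan samples, and was at least 2.03 on every array. No sample spot was saturated. Across tested genes, which are not independent replicates, arrays of 1 group correlated at a median r of 0.85 to 0.87. Control and furan arrays correlated at a median r of 0.55 at 18 h and 0.82 at 3 weeks. Control arrays of the 2 times in formalin opposed each other at a median r of -0.26, and the lowest correlation between any arrays over all probes was -0.25. The labels state the dyes and every ratio is taken against the same pool, so the direction of sample over reference was kept.

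**Figure D1:**
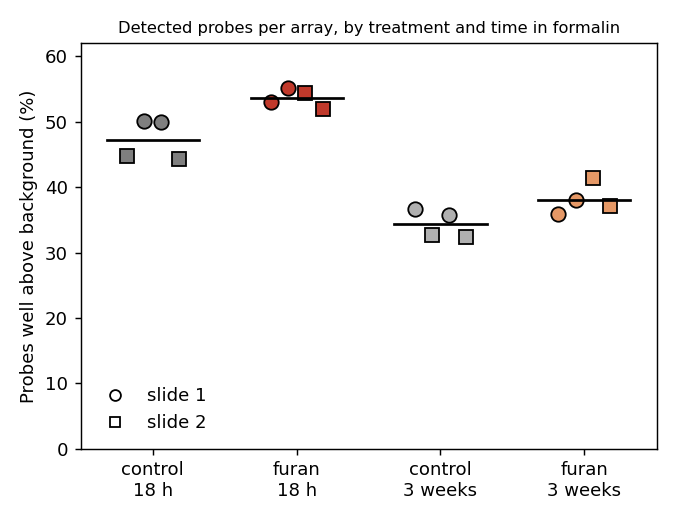
Percent of probes well above background on each of the 16 arrays by group, with circles for slide 1, squares for slide 2 and a line at the mean over 4 arrays. The 18 h furan arrays lie between 51.9% and 55.2%, above the 18 h controls, and every 3-week array lies at 41.4% or lower.

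The first comparison asked what furan changed in liver fixed for 18 h. Values are on the log2 scale, over 4 furan against 4 control samples. Among the largest rises Phlda3, a p53-induced repressor of Akt signalling, rose by 2.02 (SE 0.11), and Cdkn1a, the p21 inhibitor of the cell cycle, rose by 1.89 (SE 0.09), although its other tested probe differed by 0.02. Tubb2a, a beta-tubulin subunit, rose by 2.14 (SE 0.11). Jun, a subunit of AP-1, rose by 1.59 (SE 0.12), and Dusp6, a phosphatase that switches off ERK, rose by 1.53 (SE 0.12). Ugdh, which makes UDP-glucuronic acid, rose by 1.64 (SE 0.12), and Osgin1, a gene induced by oxidative stress, by 1.40 (SE 0.18). Gm3776 rose by 1.78 (SE 0.19) and Gm10639 by 1.54 (SE 0.18); these are alpha-class glutathione S-transferase genes whose close paralogs share sequence, so their identity is uncertain. Kansl1, part of a histone acetyltransferase complex, rose by 1.64 (SE 0.10), but its other tested probe differed by -0.32.

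Among the largest falls at 18 h, Cyp46a1, cholesterol 24-hydroxylase, fell by 2.23 (SE 0.13), Hsd17b6, a steroid dehydrogenase, fell by 1.94 (SE 0.13), and Lipc, hepatic lipase, fell by 1.49 (SE 0.09). Hpd, an enzyme of tyrosine breakdown, fell by 1.62 (SE 0.12). Hectd2, which encodes a ubiquitin ligase, fell by 1.83 (SE 0.09). Fggy, which encodes a carbohydrate kinase, fell by 1.74 (SE 0.09), while its other tested probes differed by -0.87, -0.11 and -0.04. Nfib, a transcription factor, fell by 1.62 (SE 0.10), while its other tested probes differed by -0.72, 0.07, 0.11 and 0.32. Icmt, a methyltransferase of prenylated proteins, fell by 1.52 (SE 0.10), while its other tested probes differed by -0.47 and 0.43. The noncoding RNAs Rnu2-10, a U2 spliceosomal RNA, and Rn28s1, a ribosomal RNA, fell by 1.62 (SE 0.09) and 1.56 (SE 0.12). The adjusted p of these 20 genes lay between 8.50e-06 and 0.000206, and every furan sample lay on 1 side of every control sample for each of them.

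Limma called 10681 of the 22024 genes at an adjusted p under 0.05, 4821 higher and 5860 lower, and 12272 had an unadjusted p under 0.05. A change of at least 1.5-fold was seen in 2768 of the called genes and of at least 2-fold in 340. The groups did not overlap for 8886 genes, or 40.4%, where chance gives 2.86%. The authors' deposited values split the calls differently, with 6216 higher and 4618 lower. Loess centred the log ratios of each array near 0, and 48.5% of genes were called. Rises and falls are therefore relative to that centre. Slide 1 alone gave 6087 calls and slide 2 alone 5274. Across 3018 genes with a second tested probe, the furan changes of the 2 brightest probes correlated at r = 0.12, and of the 1060 genes called on both, 458 had opposite signs. The share of probes above background was higher with furan by 6.40 points (53.7% ± 1.48, SD, n = 4, against 47.3% ± 3.18, n = 4; exact permutation p = 0.0286, the smallest possible).

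Several stress programmes moved as groups at 18 h. Of 24 measured p53 targets, 17 rose, 3 fell and 4 did not pass (18 and 3 adjusted over the list alone), and Aen, a p53-induced nuclease, rose by 1.15 (SE 0.08), with 1.19 on its other tested probe. The list as a whole was higher (camera adjusted p = 6.21e-07; adjusted p = 0.218 with an estimated correlation), with list medians of 0.74 on slide 1 and 0.67 on slide 2. Of 31 NRF2 and glutathione genes, 17 rose and 6 fell (18 and 6 adjusted over the list alone). Among them Txnrd1, a thioredoxin reductase, rose by 0.91 (SE 0.08), and Ephx1, an epoxide hydrolase, by 1.26 (SE 0.10), with 0.17 on its other probe. The list was higher (adjusted p = 0.000924; adjusted p = 0.821 with an estimated correlation; medians 0.42 and 0.34 by slide). Of 16 heat shock genes, 10 rose and 3 fell, with the same counts adjusted over the list alone. Hsp90ab1, a cytosolic chaperone, rose by 0.96 (SE 0.08), and Dnaja1, a co-chaperone, by 0.84 (SE 0.08), with 0.32 on its other probe. Hspa8, the constitutive Hsp70, rose by 0.88 (SE 0.08), with 0.00 and 0.06 on its other probes. The list was higher (adjusted p = 0.00226; adjusted p = 0.266 with an estimated correlation; medians 0.45 and 0.46 by slide). The share of probes above background moved with each of these groups.

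Of 22 DNA replication genes at 18 h, 14 rose and 0 fell (limma; 14 and 1 adjusted over the list alone). Fen1, a flap endonuclease, rose by 0.71 (SE 0.10), and the replicative helicase genes Mcm6 and Mcm2 rose by 0.69 (SE 0.10) and 0.72 (SE 0.11), Mcm2 being above background on 2 of 4 control arrays. The list was higher (adjusted p = 0.000294; adjusted p = 0.336 with an estimated correlation; medians 0.30 and 0.44 by slide). Of 17 mitotic genes, 7 rose and 3 fell, with the same counts adjusted over the list alone, and that list did not pass (adjusted p = 0.234). Of 15 immediate early genes, 8 rose and 3 fell (9 and 3 adjusted over the list alone), among them Jun, the AP-1 gene Jund, by 0.76 (SE 0.08), and Dusp1, a MAP kinase phosphatase, by 0.73 (SE 0.10). The immediate early list was higher (adjusted p = 0.0320; adjusted p = 0.287 with an estimated correlation; medians 0.40 and 0.40 by slide). Of 26 genes of the integrated stress and unfolded protein response, 10 rose and 4 fell (11 and 4 adjusted over the list alone). Ddit4, an inhibitor of mTOR signalling, rose by 0.99 (SE 0.10), Calr, a chaperone of the endoplasmic reticulum, by 0.77 (SE 0.08), and Atf4, a stress transcription factor, by 0.73 (SE 0.08), with -0.52 on its other probe. The list was higher (adjusted p = 0.0320; adjusted p = 0.287 with an estimated correlation; medians 0.31 and 0.20 by slide), but not without replicate 6 (adjusted p = 0.0551).

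Of 31 amino acid and urea cycle genes at 18 h, 17 fell and 6 rose, with the same counts adjusted over the list alone; Fah, the last enzyme of tyrosine breakdown, fell by 1.43 (SE 0.09), and Cps1, the first enzyme of the urea cycle, by 1.32 (SE 0.09). The list was lower (adjusted p = 0.00886; adjusted p = 0.821 with an estimated correlation; medians -0.32 and -0.36 by slide). Of 8 erythroid genes, 6 fell and 0 rose in limma (6 and 1 adjusted over the list alone). Hbb-bs and Hba-a1, the globins, fell by 1.06 (SE 0.13) and 1.01 (SE 0.14). Car1, a carbonic anhydrase, fell by 0.71 (SE 0.09), with -0.27 on its other probe. The erythroid list was lower (adjusted p = 0.0451; adjusted p = 0.452 with an estimated correlation; medians -0.75 and -0.45 by slide), but not without replicates 3, 6, 41 or 44, where the adjusted p reached 0.0612. Of 44 nuclear genes of oxidative phosphorylation, 15 rose and 5 fell, with the same counts adjusted over the list alone, and the list was higher (adjusted p = 0.0424; adjusted p = 0.835 with an estimated correlation; medians 0.18 and 0.12 by slide). Its members with the smallest p fell: Cyc1, cytochrome c1, by 1.01 (SE 0.08), Uqcrc1, of complex III, by 0.89 (SE 0.09), and Cox6b1, of cytochrome oxidase, by 1.02 (SE 0.10). The list's call was lost without replicates 2, 3, 4 or 41, where the adjusted p reached 0.0999, with Agilent's log ratios and with fry (adjusted p = 0.102).

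Of the genes chosen beforehand, Cyp2e1, the main furan-oxidising P450, fell at 18 h by 0.52 (SE 0.10), with -1.45 on its other probe. Gclc, the rate-limiting enzyme of glutathione synthesis, rose by 0.88 (SE 0.11), and Nqo1, a quinone reductase, by 0.68 (SE 0.11). Hmox1, heme oxygenase, rose by 0.89 (SE 0.26, adjusted p = 0.0177), but not without control 3, where the adjusted p was 0.0619. Mki67, a proliferation marker, Glul, glutamine synthetase, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by 0.20 (SE 0.10), -0.14 (SE 0.08) and -0.38 (SE 0.26), with adjusted p values of 0.111, 0.197 and 0.252.

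**Figure D2:**
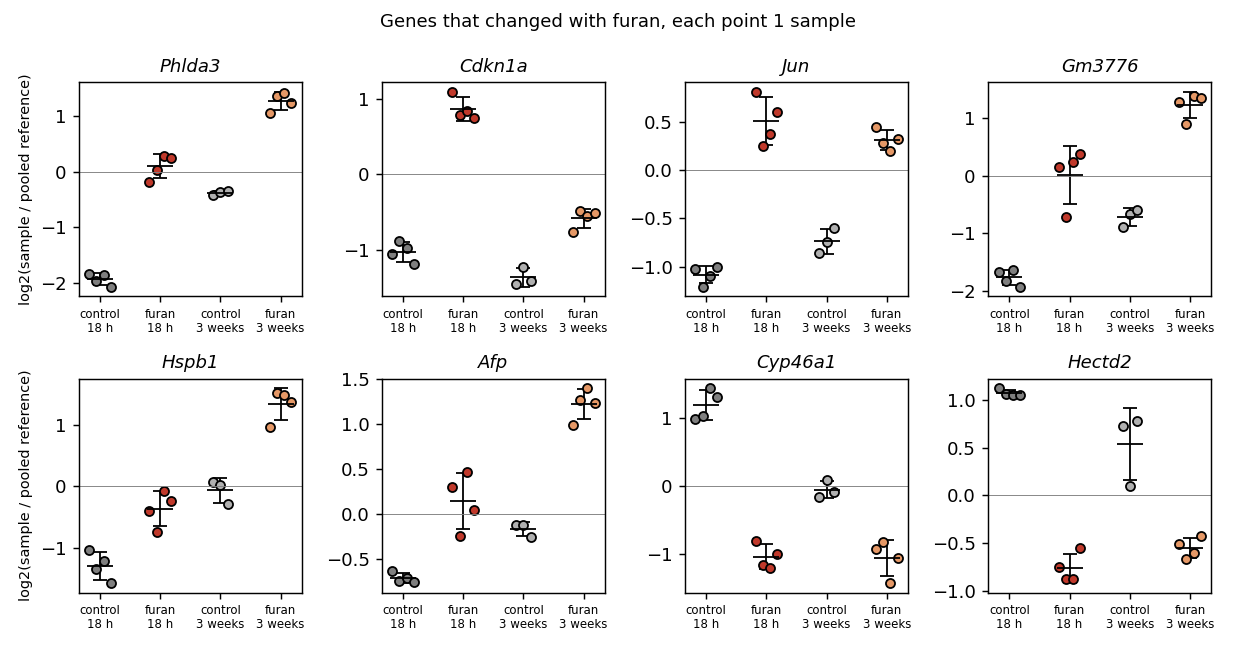
Log2 sample over reference for 8 named genes in each sample, with the mean and SD of each of the 4 groups; the 3-week control has 3 points. Phlda3 lies higher with furan at both times, by 2.02 and 1.64, and Hectd2 lower, by -1.83 and -1.08.

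The second comparison asked the same of liver fixed for 3 weeks, with 4 furan samples against 3 control samples. Gm3776, whose identity is uncertain as above, rose by 1.96 (SE 0.15), and Phlda3 rose by 1.64 (SE 0.13), with adjusted p values of 0.00288 and 0.00295. Gdf15, a stress-induced cytokine, rose by 1.35 (SE 0.17), and Hspb1, a small heat shock protein, by 1.40 (SE 0.17). Mmp12, the macrophage metalloelastase, rose by 1.42 (SE 0.13, adjusted p = 0.00573), but was not well above background on any 3-week control array, which leaves its fold poorly determined. Afp, alpha-fetoprotein, rose by 1.39 (SE 0.14), and Msln, mesothelin, by 1.32 (SE 0.18), Msln being above background on 1 of 4 control arrays. Gm10639 rose by 1.32 (SE 0.14), with 0.36 on its other probe, Cyp3a41b, a P450, by 1.18 (SE 0.18), and Cd63, a tetraspanin of late endosomes, rose 2.15-fold (SE 0.16 on the log2 scale).

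The falls at 3 weeks with a symbol were 2810410L24Rik, a noncoding transcript, by 1.20 (SE 0.18), Hectd2 by 1.08 (SE 0.16), Cyp46a1 by 1.00 (SE 0.14), and Olfr482, an olfactory receptor gene not well above background on any furan array, by 1.02 (SE 0.14). Another probe of 2810410L24Rik differed by -0.11. The calls of Gm3776 and Phlda3 held without each replicate, with an adjusted p of up to 0.0459. Mmp12 and Afp lost theirs without replicates 2 or 6, where the adjusted p reached 0.0678 and 0.0801. The other named genes, with the largest adjusted p for Hectd2 at 0.253, kept theirs in 1 to 3 of 7 such fits.

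Limma called 35 of the 22024 genes, 25 higher and 10 lower, and 3305 had an unadjusted p under 0.05. With arrays 2.1 and 2.2 as separate samples it called 381, 156 higher and 225 lower. All 35 changed by at least 1.5-fold and 26 by at least 2-fold. The groups did not overlap for 3193 genes, or 14.5%, where chance gives 5.71%. The split of the calls was 173 higher and 132 lower in the authors' deposited values and 216 and 244 with no background subtraction. The limma count was 3 without control 2 and 3 without control 6, and 776 without control 4, then 107 higher and 669 lower, the other way from the main split. It was 14, 8, 7 and 7 without furan replicates 41, 42, 43 and 44. Slide 1 alone gave 0 calls in limma, with 1700 genes at an unadjusted p under 0.05, and slide 2 gave 353, 52 higher and 301 lower. Agilent's log ratios gave 0 calls in limma, with 2871 genes at an unadjusted p under 0.05. In samples the share of probes above background was 38.1% ± 2.39 with furan (SD, n = 4) and 34.3% ± 1.77 in controls (n = 3), a difference of 3.84 points (exact permutation p = 0.0571).

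The p53 and NRF2 lists were higher at 3 weeks as well. In the 3-week medians by slide, arrays 2.1 and 2.2 were not averaged, so number 2 is among the controls of both slides. Of 24 p53 targets, 3 rose and 0 fell (limma; 8 and 0 adjusted over the list alone): Phlda3, Gdf15 and Aen, the last by 0.88 (SE 0.12), with 0.86 on its other probe. The list test gave an adjusted p of 5.71e-07 (adjusted p = 0.122 with an estimated correlation; medians 0.21 and 0.23 by slide). Of 31 NRF2 and glutathione genes, 1 rose and 0 fell (limma; 10 and 0 adjusted over the list alone). It was Gsta2, an alpha-class glutathione S-transferase, by 1.03 (SE 0.16), while Srxn1, sulfiredoxin, and Gstm1, a mu-class transferase, differed by 0.80 and 0.78 with adjusted p values of 0.0582 and 0.0645, and the other probe of Gstm1 by 0.27. The list test gave an adjusted p of 5.71e-07 (adjusted p = 0.166 with an estimated correlation; medians 0.24 and 0.26 by slide). Of 16 heat shock genes, 1 rose, Hspb1, and 0 fell (limma; 3 and 0 adjusted over the list alone), while Hsp90aa1, an inducible chaperone, and Hspa8 differed by 0.90 and 0.65 (adjusted p = 0.0582 and 0.0677), with 0.08 and 0.16 on the other probes of Hspa8. The heat shock list was higher (adjusted p = 0.00139; adjusted p = 0.166 with an estimated correlation; medians 0.09 and 0.22 by slide).

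Amino acid genes were lower as a list at 3 weeks. None of 31 was called by limma (0 and 0 adjusted over the list alone), with Hpd at -0.56, Ahcy, which hydrolyses S-adenosylhomocysteine, at -0.50 and Bhmt, a homocysteine methyltransferase, at 0.72, against the list (adjusted p between 0.171 and 0.190). The list gave an adjusted p of 0.00307 (adjusted p = 0.394 with an estimated correlation; medians -0.12 and -0.28 by slide), and it kept its call without each replicate but lost it with fry (adjusted p = 0.125). The p53, NRF2 and heat shock lists kept theirs without each replicate and with fry. The share of probes above background moved with these lists too.

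Other lists passed at 3 weeks only with some replicates left in, and the 4 that follow lost their call with fry (adjusted p of at least 0.1196). Of 24 cholesterol synthesis genes none was called (0 and 0 adjusted over the list alone), with Sqle, squalene epoxidase, at 0.62 and Insig1, a sterol sensor, at 0.54; the list was higher (adjusted p = 0.00408; adjusted p = 0.530 with an estimated correlation), but not without replicates 41 or 43 (up to 0.0605). Of 17 mitotic genes none was called (3 and 0 adjusted over the list alone), with Birc5, survivin, at 1.01 (0.60 and -0.02 on its other probes); the list was higher (adjusted p = 0.0109; adjusted p = 0.394 with an estimated correlation), but not without replicates 6 or 44 (up to 0.131). Of 22 DNA replication genes none was called (5 and 0 adjusted over the list alone), with Mcm6 at 0.89, Rfc4, of the clamp loader, at 0.46 (-0.33 on its other probe) and E2f1, a cell cycle transcription factor, at 0.49; the list was higher (adjusted p = 0.0349; adjusted p = 0.394 with an estimated correlation), but not without replicates 2, 42, 43 or 44 (up to 0.125). Of 44 oxidative phosphorylation genes none was called (1 and 0 adjusted over the list alone), with Cycs, cytochrome c, at 0.43 (-0.02 on its other probe), Ndufs6, of complex I, at 0.35, and Ndufs8, also of complex I and not well above background on any control array, at 0.72; the list was higher (adjusted p = 0.00872; adjusted p = 0.694 with an estimated correlation), but not without replicate 43 (0.0999). By slide the medians were 0.16 and 0.18 for cholesterol synthesis, 0.09 and 0.37 for mitosis, 0.17 and 0.25 for DNA replication, and 0.13 and 0.08 for oxidative phosphorylation.

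Of 20 biliary and progenitor genes at 3 weeks, 1 rose and 0 fell (limma; 3 and 0 adjusted over the list alone). It was Afp, which is a fetal hepatocyte gene, while Prom1, a progenitor surface marker, and Anxa2, an annexin, differed by 0.69 and 0.59. The list was higher (adjusted p = 0.0324; adjusted p = 0.394 with an estimated correlation), but not without replicates 4, 41 or 42 (up to 0.0788). None of 16 common reference genes was called (0 and 0 adjusted over the list alone), with Ppia at 0.49, Hprt at 0.36 and Tbp at 0.33, Tbp being above background on 1 of 4 arrays in each 3-week group; the list was higher (adjusted p = 0.0320; adjusted p = 0.530 with an estimated correlation), but not without replicates 4, 6, 41 or 43 (up to 0.129). Of 29 complement and coagulation genes none was called (0 and 2 adjusted over the list alone), with F5 and F10, coagulation factors, at -0.64 and -0.48 and Cfb, complement factor B, at -0.44; the list was lower (adjusted p = 0.0143; adjusted p = 0.530 with an estimated correlation), but not without replicates 2, 4, 41 or 44 (up to 0.0837). Of 8 erythroid genes none was called (0 and 1 adjusted over the list alone), with Alas2, of heme synthesis, at -0.44, Hbb-b2 at -0.43 and Hba-a1 at -0.42; the list was lower (adjusted p = 0.0349; adjusted p = 0.394 with an estimated correlation), but not without replicates 4, 6, 41, 43 or 44 (up to 0.141). Of 23 pericentral genes none was called (1 and 2 adjusted over the list alone), with Cyp2e1 at -0.79, Lhpp, a phosphatase, at -0.60 and Rhbg, an ammonium transporter not well above background on any control array, at 0.53, against the list; the list was lower (adjusted p = 0.0436; adjusted p = 0.530 with an estimated correlation), but not without replicates 4, 6, 41, 43 or 44 (up to 0.244). With fry the biliary list kept its call and the other 4 lost theirs (adjusted p of at least 0.1196). By slide the medians were 0.17 and 0.01 for the biliary list, 0.12 and 0.20 for reference genes, -0.16 and -0.08 for complement, -0.08 and -0.30 for erythroid and -0.13 and -0.24 for pericentral genes.

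Of the genes chosen beforehand, Cyp2e1 differed by -0.79 (SE 0.13, adjusted p = 0.0582) at 3 weeks, with -0.67 on its other probe. Cdkn1a, Nqo1 and Mki67 differed by 0.78 (SE 0.14), 0.58 (SE 0.19) and 0.57 (SE 0.16), with adjusted p values of 0.0612, 0.208 and 0.164, and were not well above background on any control array. Mki67 was above background on 2 of 4 furan arrays, and the other probe of Cdkn1a differed by -0.49. Gclc, Glul, Cyp7a1 and Hmox1 differed by 0.22 (SE 0.13), -0.21 (SE 0.12), -0.31 (SE 0.37) and 0.07 (SE 0.22), with 0.99 on the other probe of Hmox1.

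**Figure D3:**
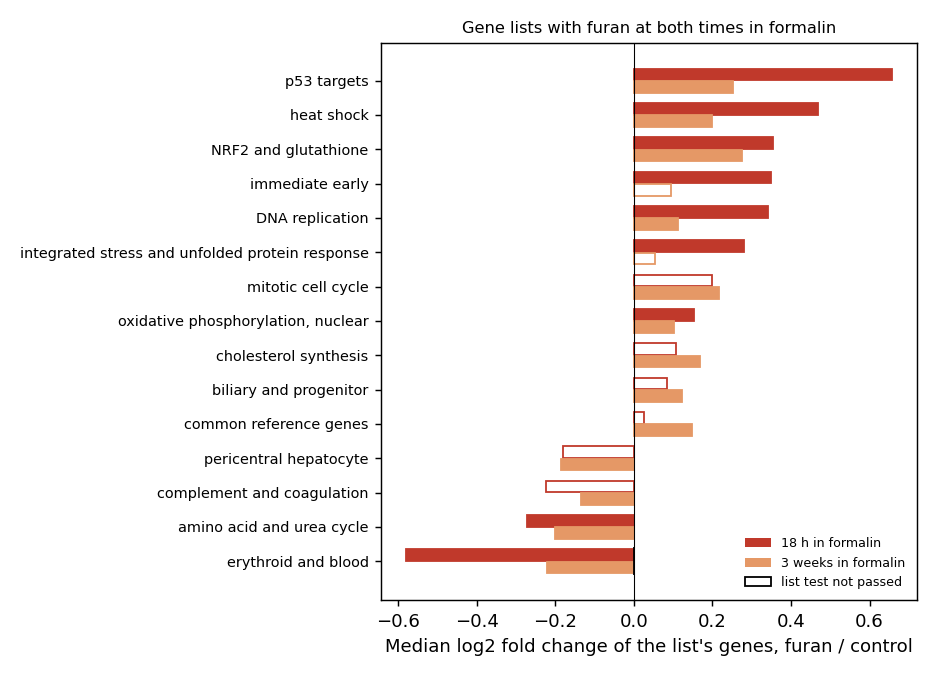
Median log2 change with furan for 15 gene lists at each time in formalin, with filled bars where the list passed the camera test at an adjusted p under 0.05. The p53 targets have medians of 0.66 at 18 h and 0.25 at 3 weeks.

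The third comparison asked whether the furan change differed between the times in formalin, over all 15 samples. Tubb2a changed less at 3 weeks by a difference of -2.21 (SE 0.16, adjusted p = 5.29e-06), as did Ugdh by -1.10 (SE 0.16) and Dusp6 by -1.15 (SE 0.18). Nfib, Hsd17b6 and Cyp46a1 fell less at 3 weeks, by differences of 1.53 (SE 0.19), 1.33 (SE 0.19) and 1.23 (SE 0.19). The other Nfib probes changed by -0.72, 0.07, 0.11 and 0.32 at 18 h and by 0.05, 0.09, -0.22 and 0.13 at 3 weeks. For Phlda3 and Gm3776 the differences were -0.38 (SE 0.16, adjusted p = 0.127) and 0.17 (SE 0.26, adjusted p = 0.698). Of 24 p53 targets, 0 had a larger change at 3 weeks and 7 a smaller one (limma; 0 and 7 adjusted over the list alone). Among them were Cdkn1a, by -1.11 (SE 0.15), with 3-week controls below background, and Bax, a promoter of apoptosis, by -1.02 (SE 0.15). Zmat3, a p53-induced zinc finger gene, also passed, but was not well above background on any 3-week array. The p53 list differed downward (camera adjusted p = 0.00464, and 0.0592 with an estimated correlation), with medians of -0.24 and -0.17 by slide. No other list passed camera for this difference. Gclc differed by -0.65 (SE 0.16, adjusted p = 0.0155), but not without replicates 6 or 41 (adjusted p up to 0.0639). Hmox1, Cyp2e1, Nqo1, Mki67, Glul and Cyp7a1 differed by -0.81 (SE 0.38), -0.27 (SE 0.15), -0.10 (SE 0.23), 0.37 (SE 0.20), -0.08 (SE 0.13) and 0.08 (SE 0.50), with adjusted p values from 0.175 to 0.937 in limma. Nqo1 and Mki67 were not well above background on any 3-week control array. The other probe of Hmox1 changed by 0.43 at 18 h and 0.99 at 3 weeks, and that of Cyp2e1 by -1.45 and -0.67. On these probes both differences had the opposite sign.

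Limma called 2816 genes for this difference, 1652 higher and 1164 lower, and 6298 had an unadjusted p under 0.05. The authors' deposited values split the calls the other way, with 1535 higher and 2197 lower. The count was 1673, 1775 and 1649 without replicates 6, 41 and 43. Slide 1 alone gave 0 calls in limma, with 4255 genes at an unadjusted p under 0.05, and slide 2 alone gave 1.

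Across the 22024 genes, which are not independent replicates, the furan changes at the 2 times correlated at r = 0.33 (rho = 0.33), and 62.6% had the same direction. Among genes called at 18 h r was 0.44, and among the 35 called at 3 weeks r was 0.78. The 25 genes called at both times, Phlda3, Gm3776, Hectd2 and Cyp46a1 among them, all had the same direction, 21 higher and 4 lower, where independent calls would share 5.47 and 2.66. With 18 h on slide 1 and 3 weeks on slide 2, which share no sample number, r was 0.22. In the other slide order, where number 2 is among the controls of both, it was 0.33. Simulated data with no effect gave r = 0.00665 and with the same effect at both times r = 0.902. The simulated effect was set on every gene and its size was not matched to the data, so 0.902 is no ceiling for the observed r. Between slides the furan changes of the same time correlated at r = 0.82 at 18 h and 0.52 at 3 weeks. At 3 weeks arrays 2.1 and 2.2 lay on different slides, so number 2 was among the controls on both sides. That can raise the 3-week value.

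**Figure D4:**
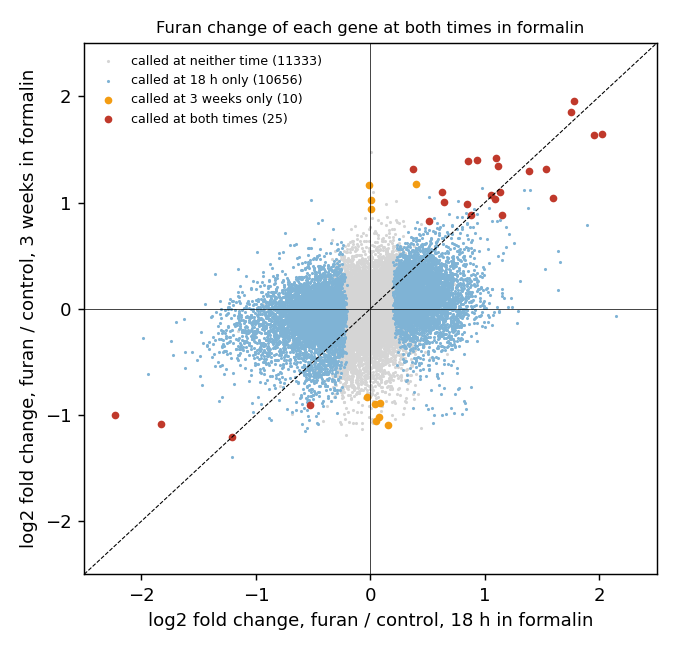
Log2 furan change at 18 h on the x axis against that at 3 weeks on the y axis, 1 point per gene, with a dashed line of equality. Colours mark genes called at neither time, at 18 h alone, at 3 weeks alone and at both, and the 25 genes called at both lie on the same side of 0 at both times.

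The last comparison asked how the time in formalin changed the profile, as 3 weeks minus 18 h over 7 and 8 samples, both treatments together. The largest rises included Rnu12, the U12 spliceosomal RNA, by 4.22 (SE 0.14), Rnu1b6, a U1 RNA, by 3.74 (SE 0.11), and Rnu2-10, by 3.40 (SE 0.17). Hbb-bs rose by 3.41 (SE 0.16), while the other globin gene Hba-a1 fell by 2.14 (SE 0.13). Rtl4, a gene derived from a retrotransposon, rose by 3.78 (SE 0.14), Slc27a4, a fatty acid transporter, by 3.34 (SE 0.16), and Gm4861, Tmem89 and Ccdc60 by 3.47 (SE 0.15), 3.40 (SE 0.22) and 3.25 (SE 0.15). Ncbp3, a cap-binding protein gene, rose by 3.59 (SE 0.15), with -0.29 on its other probe.

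Among the largest falls, Gpx1, glutathione peroxidase, fell by 3.06 (SE 0.13), and Pfn1, profilin, fell by 2.90 (SE 0.08). Aup1, a lipid droplet protein, fell by 2.87 (SE 0.08), and Uroc1, of histidine breakdown, fell by 2.80 (SE 0.11). H2-K2, a class I histocompatibility gene annotated as a transcribed pseudogene, fell by 3.18 (SE 0.14), with -2.34 on its other probe. Fdft1, squalene synthase, fell by 2.73 (SE 0.10), with -0.92 on its other probe. Cyp2d22, a P450, fell by 2.79 (SE 0.12). Gapdh, of glycolysis, fell by 2.75 (SE 0.16), while its 6 other probes ranged from -2.73 to 0.91. Cnnm3, a magnesium transport gene, and H4c14, a histone gene, fell by 3.04 (SE 0.10) and 2.95 (SE 0.12), with 0.01 and 0.37 on their other probes. Of the genes chosen beforehand, Cyp2e1 fell by 1.47 (SE 0.08), Glul by 0.27 (SE 0.07) and Gclc by 0.84 (SE 0.11). Hmox1 fell by 1.51 (SE 0.21), with 1.34 on its other probe, and Cdkn1a, not well above background on any 3-week control array, by 0.93 (SE 0.15), with 1.28 on its other probe. Mki67 fell by 0.29 (SE 0.11, adjusted p = 0.0258), but not without replicates 2, 4, 6, 41 or 42 (up to 0.0719). Nqo1 and Cyp7a1 differed by 0.02 (SE 0.11) and 0.08 (SE 0.24). Mki67 and Nqo1 were not well above background on any 3-week control array either, so these 3 values are limited by the background.

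Limma called 16208 genes, 8882 higher and 7326 lower, and 16592 had an unadjusted p under 0.05, with 13883 and 13289 called within slides 1 and 2. Loess centred the log ratios of each array near 0, although 73.6% of genes were called. Rises and falls, and their near-even split, are therefore relative to that centre. A loss of signal shared by most genes would not appear as a fall. The split was 7653 higher and 8126 lower with Agilent's log ratios and 8117 and 7932 in the authors' deposited values, and over genes above background on all 16 arrays it was 6241 and 3654. The groups did not overlap within either treatment for 10045 genes, or 45.6%, where chance gives 0.0816%. The 2 brightest probes of a gene correlated at r = 0.16 over 3018 genes, and 733 of 1705 genes called on both had opposite signs. The time in formalin cannot be told apart from the number of sections.

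With time in formalin, of 38 cytochrome P450 and conjugation genes, 26 fell and 7 rose (27 and 7 adjusted over the list alone), with Cyp4f14 and Cyp2c29, which oxidise lipids and drugs, falling by 1.94 (SE 0.08) and 2.22 (SE 0.10); adjusted p = 4.51e-05, adjusted p = 0.409 with an estimated correlation, medians -0.84 and -0.90 by slide. Of 31 amino acid genes, 23 fell and 4 rose, with the same counts adjusted over the list alone, among them Cbs, of the transsulfuration pathway, by 1.73 (SE 0.10) and Prodh, proline dehydrogenase, by 1.61 (SE 0.10); adjusted p = 7.76e-05, adjusted p = 0.439 with an estimated correlation, medians -0.59 and -0.70 by slide. Of 29 complement and coagulation genes, 22 fell and 5 rose (23 and 5 adjusted over the list alone), with Proc, protein C, falling by 2.28 (SE 0.08), Cfb by 1.88 (SE 0.08) and F11, a clotting factor above background on 2 of 4 and 3 of 4 of the 3-week arrays, by 1.64 (SE 0.09); adjusted p = 0.000413, adjusted p = 0.409 with an estimated correlation, medians -0.67 and -0.74 by slide. Of 29 acute phase genes, 19 fell and 6 rose (20 and 6 adjusted over the list alone). Itih3, a matrix-stabilising inhibitor, and Fgg, fibrinogen gamma, fell by 1.60 (SE 0.09) and 1.58 (SE 0.11). Pzp, a protease inhibitor, fell by 0.84 (SE 0.07), but it was not on the list as fixed and entered through a synonym. The list was lower (camera adjusted p = 0.0129, adjusted p = 0.534 with an estimated correlation, medians -0.81 and -0.65 by slide).

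Of 21 gluconeogenesis and glycolysis genes, 13 fell and 2 rose, with the same counts adjusted over the list alone, with G6pc, glucose-6-phosphatase, and Fbp1, fructose bisphosphatase, falling by 1.67 (SE 0.09) and 1.15 (SE 0.07); adjusted p = 0.0161, adjusted p = 0.228 with an estimated correlation, medians -0.28 and -0.44 by slide. Of 77 cytosolic ribosomal protein genes, 42 fell and 27 rose, with the same counts adjusted over the list alone. Rps2 and Rps15, of the small subunit, fell by 1.98 (SE 0.07) and 1.75 (SE 0.07), with -0.05 and -0.17 on their other probes, and Rpl14, of the large subunit, rose by 1.50 (SE 0.07), with -0.29. The ribosomal list was lower (adjusted p = 0.0319; adjusted p = 0.685 with an estimated correlation; medians -0.47 and -0.45 by slide), but not with Agilent's log ratios (0.147). Of 44 oxidative phosphorylation genes, 25 fell and 10 rose, with the same counts adjusted over the list alone. Ndufb8, of complex I, and Cox4i1, of cytochrome oxidase, fell by 2.08 (SE 0.09) and 1.72 (SE 0.09), and Cox7c, of the same oxidase, by 1.52 (SE 0.07), with -0.24 and 1.76 on its other probes. That list was lower (adjusted p = 0.0451; adjusted p = 0.685 with an estimated correlation; medians -0.25 and -0.34 by slide), but not with Agilent's log ratios (0.181) or without replicates 2, 6 or 44 (up to 0.0632). Of 24 periportal genes, 13 fell and 7 rose, with the same counts adjusted over the list alone, among them Igf1, a secreted growth factor, by 1.24 (SE 0.08). The periportal list was lower (adjusted p = 0.0451; adjusted p = 0.442 with an estimated correlation; medians -0.38 and -0.50 by slide), but not with Agilent's log ratios (0.118) or without replicates 4, 6 or 44 (up to 0.0632).

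Detection and spread moved with the time in formalin, beside all of these groups. The share of probes above background was lower at 3 weeks by -14.0 points (36.5% ± 2.85, SD, n = 7, against 50.5% ± 4.12, n = 8; exact permutation p = 0.000155, the smallest possible). Within slides 1 and 2 the differences were -15.5 and -13.0 points (exact permutation p = 0.0286 each). The median signal over background was 2.26 ± 0.128 (n = 7) and 2.42 ± 0.181 (n = 8), a difference of -0.163 that did not pass (exact permutation p = 0.0695), and -0.277 and -0.0666 within slides. The mean distance of a sample from its group mean was larger at 3 weeks by 0.06 on the log2 scale (0.25 ± 0.02, n = 7, against 0.19 ± 0.02, n = 8; exact permutation p = 0.000466), and by 0.06 within each slide (exact permutation p = 0.0571 and 0.0286). The median gene SD was 0.16 at 18 h and 0.20 at 3 weeks. These tests were two-sided.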

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

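The tests of spread between samples, of probes of the same gene and of the stretch that fixation acts on were chosen only after the results they concern were seen; those of dim probes, of RNA quality along the fixation axis and of other splits of the samples were not.

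In 378 groups of 4 samples, 18 had a sample far from the others, where chance alone gives about 1 in 20 groups, or 18.9. In 18 h controls, sample 2 lay above the others for Hectd2 (1.12 against up to 1.06), Lipc (0.87 against up to 0.67) and Atf4 (-0.62 against up to -0.69), and sample 3 for Cnnm3 (1.38 against up to 1.01), Hba-a1 (1.38 against up to 0.82) and F11 (1.05 against up to 0.65). In 18 h furan samples, 42 lay below for Gm10639 (-0.21 against at least 0.48) and above for Hbb-bs (-1.84 against up to -2.24) and Itih3 (0.59 against up to 0.27). Sample 44 of that group lay above for Uroc1 (0.67 against up to 0.35) and below for Glul (-0.18 against at least -0.03) and F11 (-0.13 against at least 0.26). In 3-week furan samples, 42 lay above for Rtl4 (2.19 against up to 1.75) and below for Fbp1 (-1.21 against at least -1.02), and 43 above for Fah (-2.06 against up to -2.31) and Tbp (0.25 against up to -0.33). Sample 41 of that group lay below for Anxa2 (1.02 against at least 1.25) and for median signal over background (2.03 against at least 2.26).

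The furan change differed between the times in formalin, by the test of the difference itself, for 39 of 87 named genes, most of them chosen for a large change at 1 of the times, against 2816 of all 22024 genes. As 3 weeks minus 18 h on the log2 scale, it was lower for Tubb2a (-2.21), Kansl1 (-1.47), Zmat3 (-1.19), Dusp6 (-1.15), Cdkn1a (-1.11), Ugdh (-1.10), Olfr482 (-1.10), F10 (-1.03), Bax (-1.02), Ddit4 (-0.97), Calr (-0.92), Hsp90ab1 (-0.88), Dnaja1 (-0.85), Mcm2 (-0.72), Alas2 (-0.66), Gclc (-0.65), Dusp1 (-0.64), Ephx1 (-0.64) and Txnrd1 (-0.43). It was higher for Hectd2 (0.75), Car1 (0.80), Ahcy (0.83), Uqcrc1 (0.91), Cps1 (0.91), Msln (0.94), Cyc1 (0.97), Cox6b1 (1.02), Icmt (1.04), Lipc (1.05), Hpd (1.06), Fah (1.09), Rn28s1 (1.15), Rnu2-10 (1.21), Cyp46a1 (1.23), Insig1 (1.30), Hsd17b6 (1.33), Fggy (1.44), Ndufs8 (1.46) and Nfib (1.53). These values are of the brightest probe of each gene. On the other tested probe the difference had the opposite sign for Kansl1, Dnaja1 and Ephx1. It did so on some of the other probes of Icmt, Fggy and Nfib. It had the same sign for Cdkn1a, F10, Car1 and Ahcy. Zmat3 was not well above background on any 3-week array, nor were Cdkn1a, Ndufs8 and Mcm2 on 3-week control arrays or Olfr482 on 3-week furan arrays, so their differences are limited by the background.

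The first pattern is the larger number of genes called for furan at 18 h, 10681, than at 3 weeks, 35. A larger spread at 3 weeks would leave the size of the changes alone, but across slides the slope of the 3-week on the 18 h change was 0.254 of that between 18 h changes, which argues against spread as the whole cause. Dim probes at 3 weeks remain open: among genes above background on all 16 arrays the ratio of calls was 52.1, over the bound of 50 set beforehand, but it fell to 6.49 with a replicate left out, so the verdict was made stricter after the value was seen. RNA of 18 h furan and control samples may also differ in quality along the fixation axis. The correlation across genes with the fixation change of controls was 0.179 and 0.182 in the slide orders. These values lie between the bounds set for and against it. Both changes contain 18 h controls with a minus sign, which can pull the values up. With the fixation change of furan arrays, which contains the 18 h furan samples with a minus sign, they were -0.112 and -0.120. That sign can pull these values down, so neither pair settles the question. The time in formalin names no difference between the livers, and no biological explanation was tested.

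The second pattern is that probes of the same gene differ in their furan change at 18 h. Different transcripts and dim second probes are argued against, since the correlation was 0.126 over pairs listed under the same accession and 0.136 over the brightest pairs. A difference between the 18 h furan and control arrays tied to the probe, not the transcript, may account for part of the 18 h calls: 2 probes of the same gene correlated at 0.116, while the same probe correlated at 0.819 between slides. At 3 weeks the furan changes of 2 probes of the same gene correlated at 0.187, so a low correlation was not particular to 18 h. Over the brightest pairs it was 0.406 at 3 weeks, so the argument against dim second probes covers 18 h only. A biological effect of furan on part of a transcript was not tested and remains open.

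The third pattern is the same for the time in formalin, where 2 probes of the same gene correlated at 0.164. Fixation that acts on the stretch a probe covers may account for it, but the number of sections changed with the time in formalin, and no biological explanation was tested.

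For the furan calls at 18 h, 1 of 35 splits of the samples, the real one, called 10681 genes and the highest other 0. At 3 weeks 1 of 35 splits, the real one, called 35 genes and the highest other 10. With 35 splits the real one can at best be 1 of 35, so these counts argue against chance but cannot exclude it. The calls at 3 weeks also depended on single replicates and on the processing. For the difference in furan effect, 2 of 100 splits called as many as the real 2816, the highest other calling 4260. The 4 splits that keep the 18 h grouping, the real one among them, called at least 2716 and all others at most 48, so these calls follow a structure of the 18 h samples. For the time in formalin 1 of 100 splits, the real one, called 16208 genes and the highest other 0.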

How the results depend on the processing

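The covariate for the share of probes above background and the next brightest probe were chosen only after the results were seen. Lists that passed kept their direction under the alternatives run for them, while fry or the block turned some lists that did not pass. The furan count at 18 h, main value 10681, was 2768 at 1.5-fold or more, 6087 and 5274 within slides 1 and 2, and 0 in limma with the covariate, where 5939 genes had an unadjusted p under 0.05; the covariate separates the 18 h groups fully, so group and covariate share 1 signal. The furan count at 3 weeks, main value 35, was 188 at an adjusted p under 0.1, 460 with no background subtraction, 305 with the authors' values, 144 over genes above background on all 16 arrays, 71 with no slide term, 353 within slide 2 (52 higher and 301 lower, against 25 and 10), 381 with arrays 2.1 and 2.2 apart, 17 with only 2.1 and 2626 with all arrays in 1 fit and the animal as a random block. In limma it was 0 with Agilent log ratios, within slide 1 and with the covariate, where 2871, 1700 and 1519 genes had an unadjusted p under 0.05. Over the averaged samples the covariate separates the 3-week groups too, with controls up to 35.8% and furan samples from 35.9%. The difference in furan effect, main value 2816, was 4366 at an adjusted p under 0.1, 1743 with Agilent log ratios, 1823 with no filter, 1 within slide 2 and 0 in limma within slide 1, where 4255 genes had an unadjusted p under 0.05. The count for time in formalin, main value 16208, was 9121 at 1.5-fold or more, 9895 over genes above background on all arrays and 3290 with the covariate. The covariate separates the times in formalin fully as well. Fewer samples or genes enter the slide and all-array settings; otherwise the cause was not tested.

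Without 1 replicate at a time the counts ranged from 9164 to 9945 at 18 h, 3 to 776 at 3 weeks (107 higher and 669 lower), 1649 to 2538 for the difference and 15577 to 15918 for time in formalin. The correlation of furan effects, 0.328 as reported, ranged from 0.242 to 0.362; it was 0.222 across slides, 0.400 over genes above background on all arrays and 0.237 with Agilent log ratios. The list calls ranged from 23 to 33, with 0 under an estimated correlation and 52 with fry, which kept 21 of the 31 reported and lost 10, 9 of them for furan at 3 weeks. Within slide 1 the distance from the group mean differed by 0.0610.

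Among cases called in the main fit or in the alternative, the sign turned with the covariate for Cdkn1a (0.0264) and Mki67 (0.0673) in the time in formalin. Neither was well above background on any 3-week control array. With the next brightest probe the sign of such cases turned at 18 h for Kansl1 (-0.32), Nfib (0.32) and Atf4 (-0.52), for the difference in furan effect of Cyp2e1 (0.77), and in the time in formalin for Ncbp3 (-0.30), Cnnm3 (0.0105), H4c14 (0.38), Gapdh (0.90), Cdkn1a (1.26), Hmox1 (1.36), Rpl14 (-0.31) and Cox7c (1.78). Among cases called in neither fit, the sign turned in 5 with the next brightest probe and in 6 with the covariate. Each other setting had fewer of these. The cause was not tested. Over all named genes and alternatives, the direction and call stayed as reported in 1219 cases at 18 h, 1257 at 3 weeks, 267 for the difference and 1374 for time in formalin, and a call was lost in 57, 136, 13 and 19. The unchanged cases include genes called in neither fit. They also include a between-array normalization that left every count as it was, and the threshold of 0.1, which cannot lose a call. The tally is therefore no rate of stability.

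The same numbers occur at both times, and the labels do not say whether a number marks the same animal, so the pairing is open: deviations of the same number correlated at 0.000736 to 0.200, median 0.0848, against a median of -0.0182 for others, and 5 of 7 correlated best with their own. With the number as a block, the oxidative phosphorylation list lost its call for time in formalin (adjusted p = 0.0511) and no other list call changed. The difference in furan effect gave 2004 calls and time in formalin 15416, the share of probes above background differed by -14.1, the distance by 0.0611, and the signal over background by -0.189, which then passed (exact p = 0.0469).

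Signal over background limits what can be seen at 3 weeks, where 32.3% to 41.4% of probes were well above it: the fold of a gene below background in a group is poorly determined.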

Other observations

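The comparison of probes on opposite strands was chosen only after its values were seen; the list tests were not.

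Of 3286 tested regions of long intergenic noncoding RNA, 261 rose and 1204 fell with furan at 18 h, or 7.94% and 36.6%, against 3523 and 3041 of 12654 protein-coding genes. At 3 weeks in formalin 1753 of these regions rose and 627 fell, compared with 18 h. All 6 tested small nuclear and nucleolar RNAs rose with time in formalin. Rnu12, Rnu1b6 and Rnu2-10 are named in the report, and Snora74a and Snora47, which guide RNA modification, and Rnu3b1, of ribosomal RNA processing, rose by 3.12, 2.43 and 2.43. With furan at 18 h, 5 of them fell, among them Rnu12 by 1.06, Rnu1b6 by 0.90, Snora47 by 0.89 and Snora74a by 0.40, while Rnu3b1 differed by -0.06. With time in formalin 140 of 294 other long noncoding RNAs rose and 73 fell, both ribosomal RNA probes rose, and of single probes telomerase RNA rose by 1.42 while the RNA of RNase MRP fell by 1.21 and an antisense RNA fell by 0.74. The difference between noncoding and protein-coding RNAs was not tested. These 6 RNAs were chosen as a class after their values were seen. The share of probes above background moved with both comparisons.

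Lists of other cell types and pathways passed camera in no comparison, and limma called none of their members with furan at 3 weeks. The adjusted p values given for them are those of camera. With fry the endothelial, hepatocyte identity, fatty acid synthesis, pancreas and neutrophil lists were lower with furan at 18 h (fry adjusted p from 0.000651 to 0.0365). The other lists below did not pass fry at 18 h. With furan at 18 h, 2 of 21 Kupffer cell and macrophage genes rose and 7 fell (2 and 6 adjusted over the list alone; adjusted p = 0.488). Of 25 stellate cell and matrix genes 6 rose and 10 fell (6 and 11; adjusted p = 0.488), of 23 endothelial genes 3 and 9 (4 and 9; adjusted p = 0.467), of 14 lymphocyte genes 1 and 3 (adjusted p = 0.619), of 8 neutrophil genes 1 and 1 (adjusted p = 0.527), of 10 adipose genes 2 and 2 (1 and 2; adjusted p = 0.945) and of 8 pancreas genes 0 and 2 (adjusted p = 0.150). Of 23 interferon genes 6 rose and 4 fell (adjusted p = 0.467), of 14 cytokine genes 3 and 3 (adjusted p = 0.649), and of 17 clock genes 2 and 3 (adjusted p = 0.931). Of 24 hepatocyte identity genes 3 rose and 11 fell (4 and 11; adjusted p = 0.150), of 20 fatty acid synthesis genes 0 and 7 (adjusted p = 0.0535), of 22 bile acid genes 6 and 5 (adjusted p = 0.952) and of 32 PPARA targets 5 and 6 (5 and 5; adjusted p = 0.911). Where no second pair is given, the counts adjusted over the list alone are the same. The median, mean and test differ in sign for the PPARA, clock and cytokine lists at 18 h.

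With time in formalin, 12 of 17 clock genes rose and 3 fell (camera adjusted p = 0.109), and 9 of 14 lymphocyte genes rose and 2 fell (camera adjusted p = 0.160). Of 8 pancreas genes 6 rose and 0 fell in limma (adjusted p = 0.161), and of 8 neutrophil genes 5 rose and 1 fell (5 and 2 adjusted over the list alone; adjusted p = 0.865). Of 20 fatty acid synthesis genes 4 rose and 11 fell (adjusted p = 0.0525), and of 32 PPARA targets 7 and 15 (adjusted p = 0.0558). Of 24 hepatocyte identity genes 6 rose and 13 fell (adjusted p = 0.0964), of 23 pericentral genes 6 and 11 (adjusted p = 0.0832) and of 22 bile acid genes 8 and 10 (adjusted p = 0.175).

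Across 745 pairs of probes on opposite strands of a region, which are not independent replicates, the furan changes correlated at r = 0.273 at 18 h and 0.336 at 3 weeks, and the changes with time in formalin at 0.363. The 18 h value compares with 0.116 for 2 probes of the same gene and with 0.105 as the highest of 1000 shuffles of the pairs.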
